A study of Macaca fascicularis with 32 samples.

How the data were processed

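Single nuclei from the substantia nigra (SN), putamen (PUT) and caudate nucleus (CN) of cynomolgus macaques, isolated with a commercial nuclei kit and run on a 10x Chromium 3′ v3 platform, were compared between PD and CT animals. The extract protocol names Macaca mulatta where the organism field names Macaca fascicularis. Per the file headers, the deposited count matrices hold UMI counts for each gene and barcode as made by the authors with Cell Ranger 7.0.1, with no normalization. The processing notes name hg38, but the gene identifiers are those of a Macaca fascicularis annotation whose release is not stated. All 6 matrices listed the same 22316 genes, of which 16297 had a symbol and 7 symbols were duplicated. The group of a matrix was known from its file name alone. The labels list 32 samples, but each matrix holds 1 set of barcodes with 1 suffix, so each was treated as 1 library and no test between groups, standard error or count of changed genes was made.

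Nuclei with at least 500 genes, at most 5% mitochondrial UMIs and a Scrublet doublet score of at most 0.25 (expected rate 0.06) were retained. This left 52639 of 56659 barcodes. Between 1.93% and 5.98% of the barcodes of a library lay above that score. No correction for free RNA was made. Counts were scaled to 10000 per nucleus and log transformed, 2000 variable genes were chosen across libraries, and 30 principal components and 15 neighbours were used for Leiden clustering at resolution 1.0 over all 6 libraries, with no batch correction. Clusters of at least 60 nuclei were clustered again (1000 variable genes, resolution 0.5). Each resulting unit was named from fixed markers (168 genes in 25 classes, 158 in the annotation) by the median of their levels relative to the highest unit of at least 50 nuclei. A unit was called mixed when its median doublet score reached 0.15 or a second family reached a relative level of 0.25 and 0.5 of the first, and unnamed when its own level was under 0.15, it had fewer than 20 nuclei, mitochondrial genes led it, its leading genes held more markers of another family than of its own, or they held none of its own while its level was under 0.5 or its depth under 1/3 of the median. Neurons with a relative level of at least 0.5 for dopaminergic markers were called dopaminergic, those with at least 0.4 for SPN markers SPNs, and SPNs were divided into direct and indirect by their marker difference, at the midpoint of 2 means. Classes are named with "-like" because they rest on markers alone. Most units drew more than 50% of their nuclei from 1 library.

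UMIs were summed over the nuclei of a class in each library. Genes with at least 50 UMIs over both libraries were compared in the 19 cases where a class chosen for its region had at least 100 nuclei in both. Other neuron-like nuclei of PUT (265 in CT, 211 in PD) and CN (478 and 381) were not among the chosen classes. Ratios of counts per total have exact conditional binomial intervals, levels exact Poisson intervals and shares exact Clopper-Pearson intervals, all at 95% and for counting error only. Log2 ratios had 0.5 UMI added to each library. The 2 genes highest and lowest in PD were named in each class by the interval bound nearest to no difference, and the 5 genes per direction shared by the compared regions of a class by the smallest such bound over regions. Genes with no symbol, mitochondrial, ribosomal, hemoglobin and sex-linked genes and markers of other classes were left out of these namings. A comparison of a single gene and the values of some named genes are not reported here, though the genes stay in their lists. For 28 fixed gene lists, the median log2 ratio of at least 5 measured members was given with its percentile among 10000 random lists matched on expression in 20 bins. The lists cover Parkinson's disease, dopamine identity, poly(ADP-ribose), homeostatic and disease-associated microglia, MHC class I and II, interferon, inflammatory cytokines, complement, reactive and homeostatic astrocytes, myelin, cholesterol synthesis, nuclear and mitochondrially encoded respiratory genes, lysosome, heat shock, proteasome, oxidative stress, iron, cell death, synaptic vesicle, postsynaptic glutamate, striatal dopamine, immediate early, blood and sex-linked genes. Agreement between regions was measured by Spearman and Pearson correlations across genes. The ratio, interval, ranking and list steps, but not the clustering, were tested on simulated data. Poisson counts were drawn from the summed SN CT profile with known changes. Of 100 genes changed by a log2 of 1, 100% ranked in the top 200 of 14420 genes, as did 80% of 100 changed by 0.5, and 95.6% of intervals held the true ratio. A list of raised genes lay at percentile 100 and a list of unchanged genes at 11.1.

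Markers, gene lists, filters, the ranking rule and most alternatives were fixed before the data were examined. Several choices were made afterwards. The automatic Scrublet thresholds marked 0, 0, 1, 4, 2 and 586 barcodes in SN CT, SN PD, PUT CT, PUT PD, CN CT and CN PD, so the fixed score replaced them. The second round of clustering and all thresholds of the naming rule were revised in about 3 rounds while tables of units with their nuclei per library were in view, and only the final version is reported. Microglia and macrophages were merged, although the plan named microglia. The depth of 500 UMIs for thinning, the use of thinned counts within the reported classes for genes and lists, and the choice of which results are followed closely among the alternatives were also set then. Thinned counts replaced reassigned classes for genes and lists after the first values had been seen. Shares with thinned nuclei use classes assigned again, in which most CN SPNs were named direct. Alternatives were nuclei with at least 200 or 1000 genes, no doublet removal, automatic doublet calls, Leiden resolution 2.0, clustering each region alone, thinned nuclei, TMM scaling (trims of 30% and 5%), a minimum of 10 or 200 UMIs, a prior of 5 UMIs, mixed units added by their leading genes, unnamed units added by their marker family or by their leading genes, and the direct SPN unit of lowest marker difference (cluster 22.3) left out, or both direct SPN units of negative difference (22.3 and 25.2) counted as indirect. The last 2 and the addition of unnamed units by leading genes were set after the results were seen, as were the genes for which shares of nuclei with a UMI are compared between classes. Gene positions came from a separate macaque annotation used for neighbours alone.

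Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9, with a random seed of 1.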

Results

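Nuclei were profiled from the substantia nigra (SN), the midbrain region that holds dopamine neurons, and from 2 striatal targets of those neurons, the putamen (PUT) and the caudate nucleus (CN, written "Caudal nucleus" in the labels), of cynomolgus macaques. Animals of the PD group belonged to a Parkinson's disease model made with an adeno-associated virus (AAV) together with poly(ADP-ribose), a polymer made by PARP enzymes, and the CT group was its control. The labels list 32 samples: 4 each for SN CT, SN PD, PUT PD and CN PD, and 8 each for PUT CT and CN CT. The deposited counts form 6 matrices, 1 for each region and treatment, with no map from barcodes to samples. Each matrix was therefore counted as 1 library, no difference has a replicate check, and treatment cannot be separated from the animals or from the library. The libraries held 9978 (SN CT), 9000 (SN PD), 10389 (PUT CT), 7702 (PUT PD), 9797 (CN CT) and 9793 (CN PD) barcodes, with totals from 18692617 UMIs (unique molecular identifiers, SN PD) to 36723856 UMIs (CN PD). After filtering, 52639 nuclei were retained, with median depths of 1243 and 1170 UMIs in SN CT and PD, 2009.5 and 1979 in PUT, and 3013 and 2641 in CN. Levels are given as CPM, the UMIs of a gene scaled to the same total in every library and class. No correction was made for free RNA, which gives UMIs to nuclei that do not make a gene. All intervals are 95% intervals and cover counting error only, so they say nothing of the spread between animals.

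The first comparison asked whether the cell makeup of SN differed, with dopaminergic neurons first. Dopaminergic neuron-like nuclei were 3.64% of retained nuclei in CT (352 of 9670) and 3.36% in PD (278 of 8276), a ratio of 0.923 whose interval (0.786 to 1.08) includes 1. Among neuron-like nuclei they were 52.1% in CT and 44.2% in PD (ratio 0.849, 0.723 to 0.996). Other neuron-like nuclei were 3.35% in CT and 4.22% in PD (1.26, 1.08 to 1.47). That excess turned to 0.919 with nuclei of at least 200 genes and 0.992 with the automatic doublet calls, and was 1.98 with thinned nuclei. Oligodendrocyte-like nuclei made up 68.6% in CT and 68.5% in PD, and oligodendrocyte precursor-like nuclei 4.35% and 3.72% (0.855, 0.736 to 0.993; 1.25 with nuclei of at least 1000 genes). Microglia or macrophage-like nuclei were 7.05% and 6.74% (0.956, 0.853 to 1.07), but the ratio was 0.280 with no doublet removal and 0.348 with at least 1000 genes. T or NK lymphocyte-like nuclei numbered 6 in CT and 65 in PD (0.0620% against 0.785%, ratio 12.7, 5.51 to 35.8). With unnamed clusters added by their leading genes they numbered 25 and 128 (5.98, 3.87 to 9.59). Barcodes carrying 2 classes' genes, left out of every class, were 9.03% of nuclei in CT and 7.94% in PD, and unnamed nuclei 3.42% and 3.94%.

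**Figure D1:**
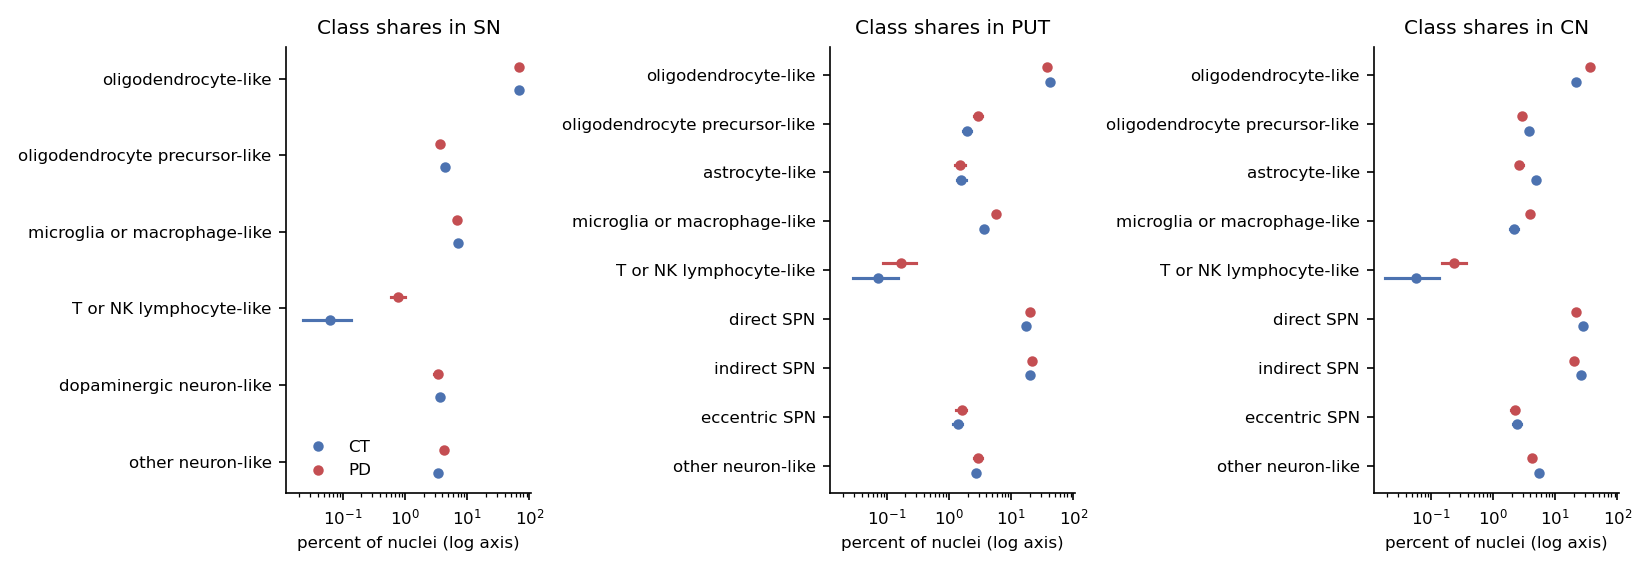
Share of retained nuclei (percent, log axis) of each class in SN, PUT and CN; points are CT (blue) and PD (red) libraries and bars are exact 95% Clopper-Pearson intervals. T or NK lymphocyte-like nuclei in SN lie at 0.0620% in CT and 0.785% in PD, and oligodendrocyte-like nuclei in CN at 21.3% and 36.2%.

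Dopaminergic neuron-like nuclei of SN had close levels of TH and SLC6A3 in CT and PD, but lay in different clusters. ALDH1A1 and NR4A2 were lower in PD over the class. The class was named by markers that include TH, SLC6A3, SLC18A2, ALDH1A1 and NR4A2. Nuclei that had lost such genes could fall outside it, so close levels within it do not show that they were kept. TH, the rate-limiting enzyme of dopamine synthesis, was 54.9 CPM in CT and 52.9 in PD (ratio 0.962, 0.803 to 1.15), and the dopamine transporter SLC6A3 was 699 and 678 (0.970, 0.923 to 1.02). The vesicular transporter SLC18A2 was higher, 677 against 782 (1.15, 1.10 to 1.21). ALDH1A1, an aldehyde dehydrogenase of ventral tier neurons, was lower, 406 against 223 (log2 -0.86), and the transcription factor NR4A2 was 74.4 against 49.6 (log2 -0.58). Of the 14 measured members of the dopamine list 5 were higher in PD, and the list's median log2 ratio of -0.050 lay at percentile 18.3 of random lists matched on expression. All 8 measured mitochondrially encoded genes were higher in PD (median 1.004, percentile 100), among them COX3 at 24 against 65.4 CPM and CYTB at 14.5 against 37.7. Mitochondrial UMIs were also a larger part of the whole SN library in PD, 0.0178% of UMIs in CT and 0.0444% in PD. Heat shock and unfolded protein response genes were mostly higher (11 of 13, median 0.39, percentile 99.8), including the mitochondrial chaperone HSPD1 (32.9 against 51.4). Cholesterol synthesis genes were mostly lower (14 of 16, median -0.25, percentile 0.260), including MSMO1 (34 against 21). Markers of myelin were lower too (13 of 14, median -0.22, percentile 0.870; -0.35 with no doublet removal or with the automatic doublet calls), but background cannot be excluded: MBP, made by oligodendrocytes, had a UMI in 87.5% of these nuclei in CT, 72.7% of microglia or macrophage-like and 41.3% of precursor-like nuclei (median depths of 14324.5, 839.5 and 1180 UMIs). The poly(ADP-ribose) list had 11 of 21 members higher and a median of 0.028 (percentile 49.8), with the TNKS tankyrase at 297 against 364 and NMNAT2 at 725 against 646. By the fixed ranking rule the genes highest in PD were HFM1 (0.378 against 20.2) and CALCR, the calcitonin receptor (6.23 against 91.3). The lowest were CERS3 (27.6 against 2.49) and P4HA3 (41.9 against 5.74). The MHC class I list had a median of 0.43 (percentile 96.4), inside the random range, but single genes stood apart, NLRC5, the transactivator of MHC class I genes, at 1.70 against 10.5 (ratio 6.17, 2.96 to 14.4) and HLA-E at 5.66 against 17.7 (3.13, 2.01 to 4.96). The peptide transporter TAP1 had 2 and 22 UMIs (14.5, 3.57 to 127), while for B2M, the light chain of MHC class I, the interval held 1 (ratio 1.47, 0.843 to 2.57). Clusters 4.2 and 4.0, both with ALDH1A1 among their leading genes, held 134 and 129 of the CT nuclei and 34 and 16 of the PD nuclei (share ratios 0.296, 0.197 to 0.435, and 0.145, 0.0804 to 0.244). Within them ALDH1A1 was 535.5 against 324 CPM (ratio 0.606, 0.4998 to 0.729) and 429.6 against 345 (0.804, 0.640 to 1.00002), and in cluster 4.1 it was 186 against 219 (1.17, 0.968 to 1.43). NR4A2 had ratios of 0.530 (0.283 to 0.920) in cluster 4.2, 0.522 (0.264 to 0.934) in 4.0 and 1.25 (0.843 to 1.88) in 4.1. The class values of ALDH1A1 and NR4A2 therefore compare different mixes of clusters. Clusters 4.1, 4.5 (led by CALCR) and 4.4 held 101, 64 and 39 of the PD nuclei. ALDH1A1 was also high in cluster 4.4, at 404 CPM in PD, and that cluster held 2 CT nuclei (share ratio 22.8, 5.90 to 195). The share ratios of clusters 4.2 and 4.0 therefore do not cover all nuclei with high ALDH1A1. Clusters of other classes were also split between libraries, such as oligodendrocyte-like clusters 1.0 (2368 CT and 116 PD nuclei) and 2.0 (175 and 2121). No batch correction was made, so a loss of nuclei from clusters 4.2 and 4.0 cannot be told apart from a difference between libraries.

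In other neuron-like nuclei of SN, antigen presentation and Parkinson's disease genes stood higher in PD. NLRC5 was 2.49 CPM in CT and 25.8 in PD, and HLA-E was 15.3 and 30.4 (3 of 5 measured MHC class I members higher, median 0.52, percentile 98.95). The Parkinson's disease gene list had 14 of 21 members higher (median 0.16, percentile 99.4), with VPS13C (257 against 315; log2 -0.14 with thinned nuclei, when it was lower) among the higher and TMEM175, a lysosomal channel (56 against 37.1), among the lower. Disease-associated microglia genes (median -0.38, percentile 2.32, SPP1 54.3 against 30.4) and myelin genes (12 of 13 lower, median -0.29, percentile 0.270) were lower, the latter at -0.029 with nuclei of at least 1000 genes and -0.10 with no doublet removal. Background cannot be excluded for either list: SPP1 had a UMI in 31.8% of these nuclei in CT and 20.9% in PD, against 28.7% and 22.9% of oligodendrocyte-like nuclei, and MBP in 75.9% in CT (median depths in CT of 6629 and 1155 UMIs). The ranking rule gave ACBD7 (0.829 against 22.2) and NLRC5 as highest, and CINP (55.1 against 9.53) and P4HA3 (51.8 against 10.2) as lowest. The largest clusters were 5.3 in CT (79 nuclei) and 5.0 in PD (85 nuclei).

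Microglia or macrophage-like nuclei of SN carried more MHC class II and interferon response RNA in PD. All 5 measured MHC class II members were higher (median log2 1.86, percentile 99.99). HLA-DPA1 was 45 against 285.5 CPM, the invariant chain CD74 was 173 against 744, and CIITA, the class II transactivator, was 84 against 307. Of 9 interferon response genes 7 were higher (median 1.01, percentile 99.99), with IFI44L at 34.5 against 240. The median was 0.26 with no doublet removal, and 0.54 over the first 9 genes. All 7 homeostatic microglia genes were lower (median -0.38, percentile 3.77), led by the fractalkine receptor CX3CR1 (441 against 84.6), although the median was 0.010 with no doublet removal. Disease-associated microglia genes went both ways (9 of 14 higher, median 0.14, percentile 70.8). GPNMB was 28.5 against 287 and CLEC7A 179 against 433 (log2 -0.025 with no doublet removal), while ITGAX was 192 against 79.3 and SPP1 551 against 211. SPP1 had a UMI in 34.3% of these nuclei in CT and 19.0% in PD, and in 37.8% and 21.9% of dopaminergic neuron-like nuclei, so background cannot be excluded for it. Complement members also split, C1QA at 82.5 against 231 and C3 at 674 against 166 (median 0.48, percentile 97.4; with no doublet removal -0.032, and 0.052 over the first members). The chemokine CXCL10, induced by interferon-γ, had 1 UMI in CT and 76 in PD (log2 5.87, 3.96 to 11.8), in a list of inflammatory cytokines whose median was 0.017. The ranking rule named KMO, an enzyme of tryptophan breakdown (0 UMIs in CT, 91 in PD), and IQGAP2 (12 against 643) as highest. The lowest were LIPJ (192 UMIs in CT, 0 in PD) and LIPF (137 and 0). Of the CT nuclei 665 of 682 lay in cluster 9.0, led by DOCK8, C3 and ITGAM. Of the PD nuclei 387 of 558 lay in sub-cluster 0 of cluster 13, led by F13A1, CLEC7A and CD74 with GPNMB and HLA-DPA1 also among its leading genes. These values therefore compare different clusters of the class. Border macrophage markers moved with them: their level relative to the highest cluster was 0.344 in cluster 9.0, which had the highest level of microglia markers. In sub-cluster 0 of cluster 13 they were at their highest and microglia markers at 0.566, and F13A1, a border macrophage marker, was 39.0 CPM in CT and 333 in PD over the class. Microglia or macrophage-like nuclei also held MHC class I transcripts, HLA-E at 155 against 206, NLRC5 at 78 against 118. The HLA-E and NLRC5 log2 ratios turned to -0.17 and -0.46 with no doublet removal, under which the share ratio of the class was 0.280.

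Oligodendrocyte-like nuclei of SN also showed higher antigen presentation and interferon genes in PD. Of 9 measured MHC class I genes 8 were higher (median log2 1.09, percentile 100). NLRC5 was 2.97 against 66.9 CPM, TAP1 2.75 against 18.8, HLA-E 13.1 against 67.5 and B2M 7.49 against 21. All 5 MHC class II genes were higher (median 1.56, percentile 100), with HLA-DRA at 7.38 against 28.8 and CD74 at 16.8 against 49.8. CD74 was also higher in precursor-like (ratio 2.40), dopaminergic (2.25) and other neuron-like nuclei (2.88). In microglia or macrophage-like nuclei it was 173 against 744, so free RNA cannot be excluded as a source of class II RNA here. Of 13 interferon response genes 9 were higher (median 0.73, percentile 100), with MX1 at 1.54 against 13.4 and IFI44L at 13.1 against 45.6. The median was 0.25 with thinned nuclei and 0.33 with a minimum of 200 UMIs, both over only 8 members, and 0.78 with thinned nuclei over the first 13. In the same nuclei complement genes were higher (5 of 6, median 0.71, percentile 99.9), C1QA at 14 against 23.5. C3 was lower at 20.6 against 9.98, and both are the directions seen in microglia or macrophage-like nuclei. All 10 mitochondrially encoded genes were higher (median 0.75, percentile 100), as was their part of the whole SN library (0.0178% of UMIs in CT, 0.0444% in PD). So were 13 of 16 cholesterol synthesis genes (median 0.30, percentile 99.9), HMGCS1 at 8.81 against 24.2. The Parkinson's disease gene list (median 0.16, percentile 98.6) was -0.015 with nuclei of at least 1000 genes (0.056 over the first members), and postsynaptic glutamate genes had a median of 0.18 (percentile 98.3). Myelin genes had a median of -0.063 (percentile 11.4), with MBP lower (log2 -0.45) and TF at 749.8 against 489. The ranking rule named CLDN16 (0.330 against 33.9) and EFHB (0.440 against 29.4) as highest and CMTM8 (59.7 against 3.38) and CFAP157 (15.5 against 0.844) as lowest. The CT nuclei lay mostly in clusters 1.0, 0.2 and 0.0, and the PD nuclei in 2.0 (2121 of 5671, led by IGKC, NLRC5 and HLA-E), 2.1 and 0.1. Background cannot be excluded for IGKC, which had UMIs in every compared class of SN PD. In oligodendrocyte precursor-like nuclei NLRC5 was 16.7 against 42.2 (ratio 2.53, 1.09 to 6.36), HLA-E 11.1 against 33.3 (3.00, 1.10 to 9.44) and TAP1 had 3 and 12 UMIs (4.80, 1.30 to 26.5). BTN3A2, a butyrophilin, was 24.1 against 131 and LRRK2, a Parkinson's disease kinase, 18.5 against 88.9 there, while CNTN3 was 118 against 13.3 and CACNA1B 92.5 against 26.7. No list there lay outside the range of random lists.

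In PUT, the shares of spiny projection neurons (SPNs) depended on how these were divided, and those of most glia on the filters. Direct pathway SPNs were 17.5% in CT and 19.99% in PD (ratio 1.14, 1.06 to 1.22; 0.986 with the automatic doublet calls) and indirect pathway SPNs 19.9% and 21.7% (1.09, 1.02 to 1.17). Among neuron-like nuclei alone these ratios were 1.03 (0.956 to 1.10) and 0.980 (0.916 to 1.05). The direct SPN excess rested on cluster 22.3 (73 nuclei in CT, 229 in PD), whose direct minus indirect marker difference was -0.33. Without it the ratio was 1.003. With direct SPN clusters of negative difference counted as indirect SPNs, the direct ratio was 0.984 and the indirect ratio 1.21. Oligodendrocyte-like nuclei were 41.9% and 37.8% (0.903; 1.09 with at least 1000 genes). Precursors were 1.93% and 2.94% (1.53, 1.25 to 1.87) and microglia or macrophage-like nuclei 3.65% and 5.65% (1.55, 1.34 to 1.79; 0.748 with at least 1000 genes). Astrocyte-like nuclei were 1.58% and 1.53% (0.969, 0.751 to 1.25), but the ratio was 0.393 with at least 200 genes, 0.606 with at least 1000 genes and 0.7003 with mixed barcodes added. T or NK lymphocyte-like nuclei numbered 7 in CT and 12 in PD (2.30, 0.833 to 6.88, an interval that includes 1). Mixed barcodes were 8.14% in CT and 4.72% in PD. With them added to their leading family the microglia or macrophage ratio was 1.16 and the precursor ratio 1.16.

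Cholesterol synthesis genes were lower in PD in both main SPN classes of PUT. In indirect SPNs 15 of 16 measured members were lower (median log2 -0.66, percentile 0), with MSMO1 at 49.1 against 19.9 CPM and HMGCS1, which makes HMG-CoA, at 24.2 against 10.3. In direct SPNs 14 of 15 were lower (median -0.58, percentile 0), MSMO1 at 52.7 against 19. With thinned nuclei the direct SPN median was -0.072 over the 6 members that still passed the minimum, and -1.13 over the members measured without thinning. In indirect SPNs it was -0.51 over 7 members. With the classes of thinned nuclei assigned again, it was -0.62 over 7 members in direct and -0.051 over 5 members in indirect SPNs. Nuclear-encoded respiratory chain genes were lower in direct SPNs (15 of 20, median -0.23, percentile 1.62; with thinned nuclei -0.12 over 9 members and -0.42 over the first 20). In indirect SPNs mitochondrially encoded genes (9 of 10 lower, median -0.58, percentile 0.10; the whole PUT library held 0.0224% mitochondrial UMIs in CT and 0.0146% in PD), heat shock genes (11 of 13, median -0.26, percentile 2.29) and disease-associated microglia genes (median -0.43, percentile 0.270; -0.085 with a minimum of 10 UMIs, over 13 members) were lower. In the last list SPP1 lay at a background level, with a UMI in 21.8% of indirect SPNs, 22.6% of precursors and 15.8% of astrocytes in CT (median depths of 4623.5, 1259 and 1427 UMIs) and in 11.3%, 7.08% and 9.09% in PD. In direct SPNs SPP1 was 50.6 against 23.4 CPM, while MBP, made by oligodendrocytes, was 92.8 against 108. Lower background in PD cannot be excluded for the other lists that were lower in these SPNs. The Parkinson's disease gene list was lower in direct SPNs (12 of 18, median -0.16, percentile 2.28), TMEM175 at 62.8 against 36 and UCHL1 at 170.3 against 119. Striatal dopamine signalling genes had medians of -0.078 and -0.066 in direct and indirect SPNs (percentiles 15.6 and 13.9). By the ranking rule ABO, a glycosyltransferase of blood groups, was highest in both (0.573 against 72.5 in direct, 0.522 against 64.8 in indirect SPNs), followed by NKD2 (1.37 against 44.1) in direct and ACBD7 (0.313 against 34.1) in indirect SPNs. The lowest were HLA-DPB1 (9.51 against 0.151) and RPE65 (9.16 against 0.151) in direct and KBTBD12 (15.9 against 0.836) and P4HA3 (8.46 against 0.279) in indirect SPNs. Cluster 22.0 held most CT and 22.2 most PD nuclei of direct SPNs, and sub-clusters 0 and 1 of cluster 25 those of indirect SPNs. Eccentric SPNs had STK32B (6.34 against 155) and GRM8 (55.5 against 439.8) highest and CADPS2 (88.7 against 2.16) and CHSY3 (1052 against 198) lowest, with no list outside the random range.

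Oligodendrocyte-like nuclei of PUT had lower RNA for energy metabolism and protein folding in PD, but lower background in PD cannot be excluded as a source. PCP4, a gene of SPNs, was 427 against 173 CPM in these nuclei. It was 351 against 149 in astrocyte-like and 573 against 206 in microglia or macrophage-like nuclei. All 10 mitochondrially encoded genes (median log2 -0.94, percentile 0; CYTB 62.3 against 29), 17 of 20 nuclear-encoded respiratory chain genes (median -0.50, percentile 0; -0.17 with at least 1000 genes and -0.30 with a minimum of 200 UMIs, over 14 members) were lower. Mitochondrial UMIs were 0.0224% of the whole PUT library in CT and 0.0146% in PD. Of 16 heat shock genes 14 were lower (median -0.53, percentile 0.060; HSP90AB1 109.9 against 49.4). So were cholesterol synthesis genes (12 of 14, median -0.45, percentile 0.720; -0.10 over 7 members with a minimum of 200 UMIs, -0.16 over 11 with thinned nuclei and -0.41 over the first 14, -0.72 with at least 1000 genes and -0.56 over the first 14). Iron handling genes (9 of 10, median -0.34, percentile 1.82) and myelin genes (10 of 15, median -0.12, percentile 1.45; -0.057 with TMM scaling) were lower. Background cannot be excluded for the disease-associated microglia list (median -0.60, percentile 0.010). Its member SPP1 had a UMI in 27.4% of these nuclei in CT and 15.2% in PD. It was lower in every other PUT class whose genes were compared too, with 15.8% and 9.09% in astrocyte-like nuclei. Lists of neuronal genes went both ways in these nuclei, with medians of -0.45 for synaptic vesicle genes (percentile 0.180; -0.26 with at least 1000 genes or, over 10 members, a minimum of 200 UMIs) and -0.21 for striatal dopamine signalling genes (percentile 2.45; -0.44 with a minimum of 10 UMIs, over 14 members), while postsynaptic glutamate genes had 0.14 (percentile 98.3; 0.013 with thinned nuclei). Such lists hold background in glia: PCP4, an SPN gene, had a UMI in 37.1% of these nuclei in CT and 20.01% in PD, and in 38.2% and 16.4% of astrocyte-like nuclei (median depths of 1048 and 1427 UMIs in CT, 1208 and 1276 in PD). DMD, which encodes dystrophin, was 52.5 against 783 CPM and EFHB 0.214 against 29, while CPB1 (21.8 against 0.828) and NPVF (15 against 0.552) were lowest. The CT nuclei lay mostly in clusters 1.1 and 6.0 and the PD nuclei in 7.1 and 6.1.

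Among other glia of PUT, microglia or macrophage-like nuclei had FSTL4 (35.4 against 445 CPM) and TMEM114 (16.1 against 241) highest and LIPJ (61 UMIs in CT, 0 in PD) and LIPF (55 and 0) lowest. Cluster 9.1 held most of them in both libraries. Their disease-associated microglia list had a median log2 of -0.54 (percentile 0.030; AXL 219 against 362) that turned to 0.21 with a minimum of 10 UMIs, over 13 members. Its member SPP1 was at background, with a UMI in 21.3% of these nuclei in CT and 5.65% in PD and in 22.2% and 10.00% of direct SPNs (median depths in CT of 785 and 4783.5 UMIs). Their striatal dopamine list (median -0.47, percentile 0.270) is not read as expression. PENK, a neuropeptide of indirect SPNs, had a UMI in 15.6% of these nuclei in CT and 6.14% in PD, against 13.6% and 4.81% of oligodendrocyte-like nuclei (median depth 1048 UMIs in CT) and 36.5% and 24.4% of indirect SPNs (4623.5 UMIs). Precursor-like nuclei had LRRK2 (40.2 against 157) among the highest. The ranking rule named SPP1 and PCP4 as their lowest, but both were at background, with a UMI in 22.6% and 31.7% of these nuclei in CT (median depth 1259 UMIs) and in 21.3% and 39.2% of microglia or macrophage-like nuclei. Astrocyte-like nuclei had DPP10 (199 against 1210) and KCNMA1 (59.3 against 401) highest and AFF2 (52 UMIs in CT, 0 in PD) and GALNTL6 (326 against 20.4) lowest.

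In CN, oligodendrocyte-like nuclei held a larger share in PD and neurons a smaller one. Oligodendrocyte-like nuclei were 21.3% in CT and 36.2% in PD (ratio 1.70, 1.61 to 1.80) and all neuron-like nuclei 61.9% and 48.0% (0.776). Direct SPNs were 28.3% and 21.4% (0.755, 0.711 to 0.802), indirect SPNs 25.7% and 20.2% (0.789, 0.741 to 0.839). Among neuron-like nuclei alone these ratios were 0.973 (0.917 to 1.03) and 1.02 (0.955 to 1.08). Astrocyte-like nuclei were 4.99% and 2.67% (0.535; 1.01 with at least 1000 genes, 0.0681 with at least 200), precursors 3.84% and 2.92% (0.761; 2.40 with at least 1000 genes). Microglia or macrophage-like nuclei were 2.20% and 3.88% (1.77; 7.53 with at least 1000 genes) and other neuron-like nuclei 5.49% and 4.17% (0.759; 0.993 with at least 200 genes). Eccentric SPNs, at 2.44% and 2.24%, had a ratio of 0.0351 with at least 200 genes, 0.0631 with no doublet removal and 0.0693 at the higher clustering resolution. T or NK lymphocyte-like nuclei numbered 5 and 22 (4.19, 1.55 to 14.2). With at least 1000 genes the oligodendrocyte ratio was 8.62. Over all CN nuclei the median depth was lower in PD (2641 UMIs, 3013 in CT), but within classes the mean depth was higher, at 1214 against 910 UMIs per oligodendrocyte-like nucleus and 5928 against 4406 per direct SPN.

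SPNs of CN again had lower cholesterol synthesis genes in PD. All 16 measured members were lower in direct SPNs (median log2 -0.60, percentile 0.030; -0.45 with TMM), MSMO1 at 48.6 against 20.9 and SQLE at 58 against 34 CPM. All 16 were lower in indirect SPNs (median -0.63, percentile 0; -0.48 with TMM), MSMO1 at 46.6 against 18.5 and DHCR7 at 6.30 against 2.76. In indirect SPNs all 13 heat shock genes (median -0.55, percentile 0.140; HSPD1 29.8 against 17) and 5 of 6 MHC class I genes (median -0.73, percentile 1.53; -0.099 with a minimum of 10 UMIs, over 9 members; PSMB9, an immunoproteasome subunit, 6.91 against 1.84) were lower. The median of all measured genes was -0.15 in both classes, so small negative values there lie at the level of all genes. With TMM the medians of the Parkinson's disease, striatal dopamine, synaptic vesicle and poly(ADP-ribose) lists turned to between 0.021 and 0.084, the lysosome list in direct SPNs to 0.023 and the iron list in indirect SPNs to 0.0014. ABO was highest in both classes (0.829 against 54.5 in direct, 0.407 against 50.05 in indirect SPNs), followed by ACBD7 (1.01 against 25.9 and 0.712 against 28.7). The lowest were KBTBD12 (18.3 against 0.863 and 16.3 against 1.01), PRR22 in direct (7.74 against 0.259) and EVC in indirect SPNs (22.7 against 1.93). Clusters 21.2 and 23.0 held most CT nuclei and 21.1 and 23.3 most PD nuclei. Eccentric SPNs had CDH13 (39.7 against 388) and UNC5D (139 against 1105) highest and PIEZO2 (60.8 against 3.77) and TMEM144 (79.4 against 12.3) lowest, with clusters 10.3 in CT and 10.2 in PD.

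Glia of CN shared features with those of PUT. In oligodendrocyte-like nuclei 15 of 20 respiratory chain genes (median log2 -0.53, percentile 0), all 9 disease-associated microglia genes (median -0.48, percentile 0.730; -0.28 with thinned nuclei; background not excluded) and 12 of 13 heat shock genes (median -0.42, percentile 1.13) were lower. So were 20 of 24 proteasome genes (median -0.38, percentile 0.570; -0.17 with a minimum of 200 UMIs, over 7 members) and 9 of 15 myelin genes (median -0.14, percentile 1.15; 0.038 with thinned nuclei). Lower background in PD cannot be excluded for the respiratory chain, heat shock and proteasome lists either. Neuron-like nuclei, a possible source of free RNA, were 61.9% of CN nuclei in CT and 48.0% in PD. Postsynaptic glutamate genes were higher (13 of 16, median 0.32, percentile 100). DMD was 89.1 against 1268 CPM and CLDN16 had 0 UMIs in CT and 84 in PD. CMTM8 (208 against 17.4) and BOP1 (41 against 2.98) were lowest. Cluster 6.0 held most CT and 6.1 most PD nuclei. Astrocyte-like nuclei had 5 of 7 reactive astrocyte genes higher (median 0.33, percentile 98.4), CD44 at 53 against 125 and the matrix protein TNC at 195 against 286, and 6 of 7 postsynaptic glutamate genes (median 0.40, percentile 99.15). DPP10 (377 against 2373) and WIF1 (38.1 against 220.5) were highest and AFF2 (238 against 11.4) and GALNTL6 (689 against 65.9) lowest. Precursors had CHL1 (45.2 against 194) among the highest and ATP13A5 (827 against 252) among the lowest. Microglia or macrophage-like nuclei had FSTL4 (6.0 against 339.6) and MGLL (18 against 161) highest and RNLS (2202 against 111) and CDH13 (306 against 54.4) lowest.

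Across the 19 comparisons of a class in a region, 283 list medians were measured. Of these 18 lay above and 31 below the central 95% range of random lists. Independent lists would give about 7.08 on each side, but these lists are not independent. No median left the random range for the poly(ADP-ribose) list (18 comparisons, medians from -0.20 to 0.23), lysosome and autophagy (16, -0.24 to 0.19), homeostatic astrocyte (14, -0.23 to 0.25), oxidative stress (11, -0.38 to 0.017), cell death and DNA damage (10, -0.35 to 0.044), inflammatory cytokines (6, -0.51 to 0.084), homeostatic microglia (4, -0.38 to 0.26), immediate early genes (4, -0.55 to -0.15) or the dopamine list (3, -0.050 to 0.27). The blood and sex-linked lists had too few measured members for a median.

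**Figure D2:**
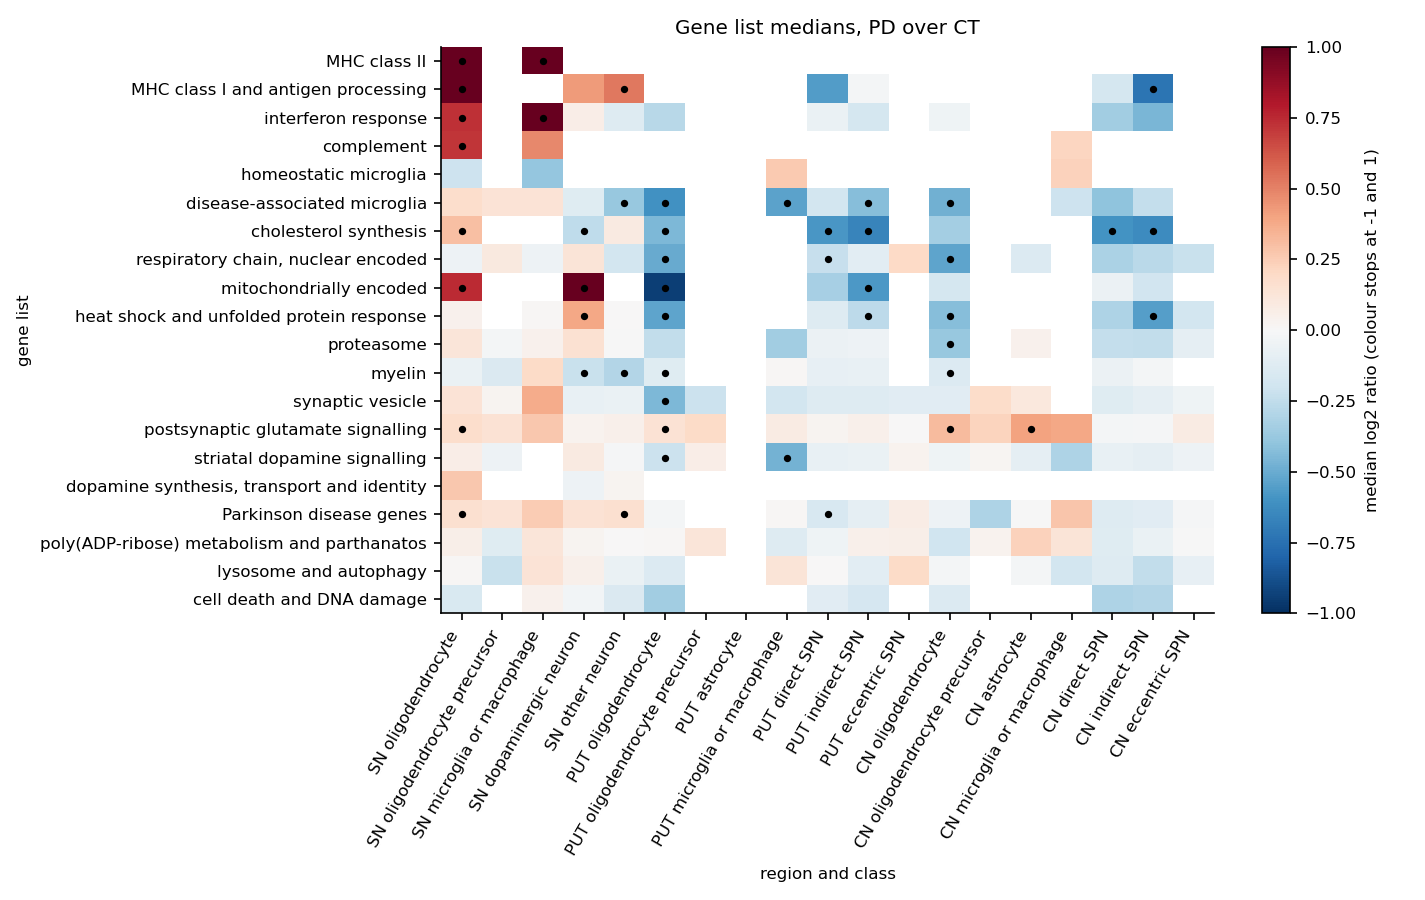
Median log2 ratio (PD over CT, colour, stopping at -1 and 1) of 20 gene lists (vertical axis) in each region and class (horizontal axis); white cells had fewer than 5 measured members and dots mark medians outside the central 95% range of random lists. MHC class II stands at 1.56 in SN oligodendrocyte and 1.86 in SN microglia or macrophage nuclei, and cholesterol synthesis between -0.66 and -0.58 in the 4 direct and indirect SPN columns.

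Log2 ratios of the same class were then compared between regions, which use separate libraries. The labels do not say whether regions share animals, and genes are not independent replicates. Oligodendrocyte-like nuclei of PUT and CN had a Spearman correlation across genes of 0.603 (9058 genes), against 0.344 for SN and PUT and 0.365 for SN and CN, and 47.9% of 8958 genes went the same way in all 3 regions, where independent signs would give 25%. For SPNs of PUT and CN it was 0.561 in direct (0.338 with thinned nuclei), 0.578 in indirect (0.352 with thinned nuclei) and 0.349 in eccentric SPNs. For astrocytes it was 0.403 (0.2197 with a minimum of 10 UMIs, 0.6001 with one of 200). For microglia or macrophages it was 0.205 to 0.350, the latter for PUT and CN (0.554 with a minimum of 200 UMIs). For precursors it was 0.123 for SN and PUT (0.0642 with reassigned thinned nuclei) to 0.257 for PUT and CN (0.184 with a minimum of 10 UMIs, 0.442 with one of 200). The genes furthest apart in all regions of a class were DMD, ARHGAP29, EFHB, COL23A1 and NAALAD2 (higher) and CMTM8, BOP1, HS3ST4, CPB1 and VEGFD (lower) in oligodendrocytes, with DMD at 85.9 against 433 CPM in SN. In microglia or macrophages they were FSTL4, MDGA2, SMIM35, CD74 and SAMD4A (higher) and RNLS, RTTN, ASTN2, RARS2 and TMEM144 (lower), and in precursors EHD4, NRG3, CTNNA2, GALNT13 and GPR158 (higher) and ATP13A5, KCNT2, TSHZ2, WSB1 and CADPS (lower). In PUT and CN, direct and indirect SPNs both had ABO, ACBD7, NKD2 and SP100 higher and KBTBD12, HLA-DPB1, EVC and WDR88 lower, with EFHB (higher) and RPE65 (lower) in direct and FAM83B (higher) and CDH23 (lower) in indirect SPNs. Eccentric SPNs had CDH13, CLSTN2, STK32B, GRM8 and PALLD higher and PIEZO2, HS6ST3, ZNF804B, STK3 and TMEM144 lower, and astrocytes DPP10, KCNMA1, KCNQ5, MOXD1 and KIRREL3 higher and AFF2, GALNTL6, LMNTD1, GSAP and CTNNA2 lower.

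**Figure D3:**
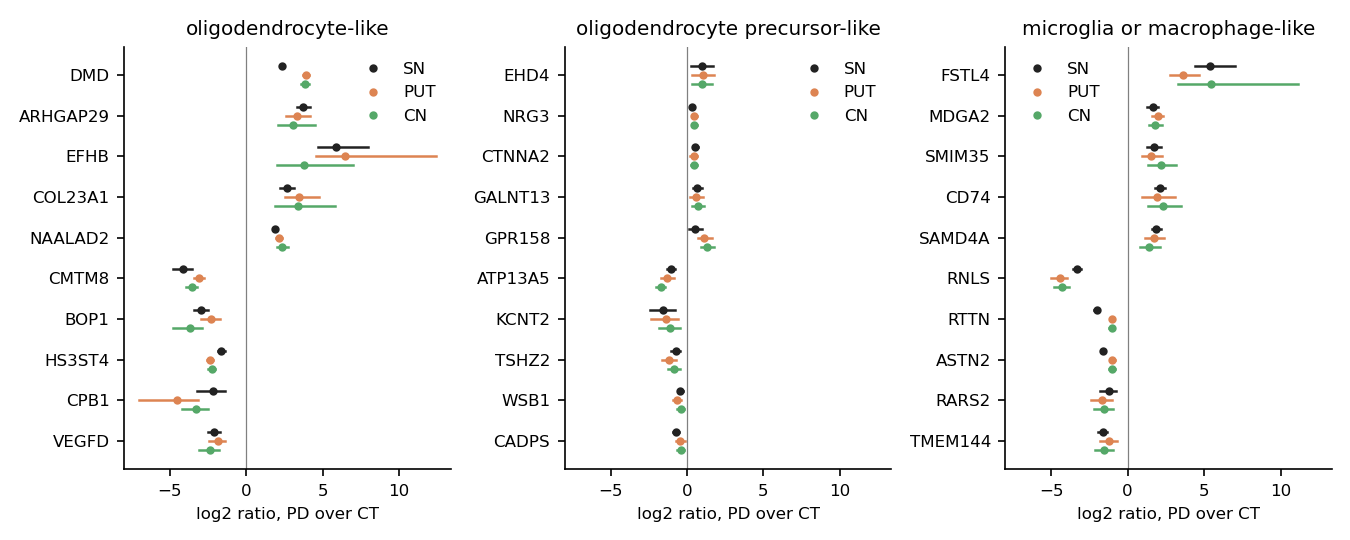
Log2 ratio (PD over CT, horizontal axis) of the 5 highest and 5 lowest genes shared by SN (black), PUT (orange) and CN (green) in 3 classes; bars are exact 95% intervals, counting error only. In oligodendrocyte-like nuclei DMD lies above 0 and CMTM8 below 0 in all 3 regions, as the ranking rule requires.

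The last comparison set the CT libraries of the striatum beside each other. PDE10A, a phosphodiesterase of SPNs, was higher in PUT than in CN (ratio 1.62, 1.60 to 1.64 in direct and 1.66, 1.64 to 1.68 in indirect SPNs), as was ADCY5, the main striatal adenylyl cyclase (1.39 and 1.52). The dopamine receptor DRD3 was lower in PUT (0.437 and 0.487), PDYN, the dynorphin precursor, was 0.0997 in direct SPNs, and the indirect SPN markers DRD2 and ADORA2A were 2.21 and 2.42 there. The direct SPNs lay in different clusters, mostly 22.0 in PUT CT and 21.2 and 19.1 in CN CT, and cluster 19.1, with PDYN among its leading genes, held 13 nuclei of PUT CT and 386 of CN CT. Clusters 22.3 and 25.2, of negative marker difference, held 73 and 92 of the 1690 direct SPNs of PUT CT. In PUT CT, DRD2 was 37.0 CPM in direct and 548 in indirect SPNs, and DRD1 was 3.78 in direct SPNs. Indirect SPNs counted as direct therefore cannot be excluded for the DRD2 and ADORA2A ratios. In indirect SPNs DRD2 was 1.48 and the adenosine receptor ADORA2A 1.69. Oligodendrocyte-like nuclei made up 68.6% of SN, 41.9% of PUT and 21.3% of CN nuclei in CT, and 52.2%, 12.6% and 1.21% of nuclei with at least 1000 genes.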

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

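All tests in this part were chosen after the results were seen, and the test of free RNA was revised after its first values were seen.

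Intervals on opposite sides of no difference, or lists outside opposite ends of the central 95% range of random lists, marked the following regions, and the differences between regions were not tested. Direct SPN-like nuclei had a share ratio (PD over CT) of 1.14 in PUT and 0.755 in CN, and indirect SPN-like nuclei 1.09 and 0.789. The direct SPN ratio in PUT was 1.003 without cluster 22.3, so it then no longer stood apart from no difference. As a share of neuron-like nuclei alone, no SPN ratio stood apart from no difference. Direct SPNs then had 1.03 in PUT and 0.973 in CN, and indirect SPNs 0.980 and 1.02. All neuron-like nuclei had 1.11 in PUT and 0.776 in CN. Oligodendrocyte-like nuclei had 1.70 in CN and 0.903 in PUT. Oligodendrocyte precursor-like nuclei had 1.53 in PUT, 0.855 in SN and 0.761 in CN. Other neuron-like nuclei had 1.26 in SN and 0.759 in CN. In oligodendrocyte-like nuclei the cholesterol synthesis list had a median log2 of 0.30 in SN and -0.45 in PUT, and mitochondrially encoded genes had 0.75 in SN and -0.94 in PUT. The mitochondrial part of all UMIs went the same ways, 0.0178% in CT and 0.0444% in PD for SN and 0.0224% and 0.0146% for PUT. Nuclei in no named class were marked when far more came from PD: cluster 8.2, unnamed and led by IRF4 and IGKC, held 48 nuclei of SN PD and 1 of SN CT, and cluster 12.3, mixed and led by GPNMB, held 410 and 7.

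Genes far apart between PD and CT in every compared region of a class, such as DMD, CMTM8 and RNLS, formed the first pattern. The median size of the log2 ratio was 1.10 with thinned nuclei and 1.15 without, a ratio of 0.955. That argues only against a larger weight of deep nuclei in the class sums as the whole cause. Thinning leaves the expected share of each gene within a nucleus as it was, and the genes were chosen from the same counts. Other effects of depth were therefore not tested. A difference between the genomes of the CT and PD animals may contribute: of 498 such genes 476 (95.6%) had a position, and 14.1% of those had a neighbour in the set, against 9.66% (6.09% to 13.4%) in random sets matched on expression from 10300 genes. The margin is small, the neighbours RNLS, LIPJ and LIPF on chromosome 9 had been noticed first, and neighbouring genes can share regulation or be paralogs. Treatment was not tested apart from the animals.

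The second pattern was the higher immune gene RNA of SN PD, tested in oligodendrocyte-like nuclei alone (NLRC5 2.97 CPM in CT, 66.9 in PD) although NLRC5 was also 1.70 and 10.5 in dopaminergic and 2.49 and 25.8 in other neuron-like nuclei. The MHC class I list had a median log2 of 1.52 with thinned nuclei and 1.09 without, over the members measured without thinning. For that list alone, this argues against a larger weight of deep nuclei in the sums, but not against other effects of depth. For the interferon response list thinning does not decide, because its result depended on the members. That median was 0.73 without thinning, 0.25 with it over the 8 members still measured, and 0.78 with it over the first members. Free RNA from microglia or macrophages, which could reach every class, and expression in these nuclei cannot be told apart. MHC class II genes were not tested. The test used only the 17 MHC class I and interferon response members that were higher in PD, a choice that can raise the median. Their excess in PD had a median of 12.3 times (0.205 to 35.3) the level given by a leak of 1.54%, the median of 14 markers. That leak ran from 0.538% to 23.1%, and at the highest (C1QB) the median was 0.814, with 5 members above 1. A response to the treatment was not tested.

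The third pattern was the mixed microglia or macrophage and oligodendrocyte barcodes of SN. Of microglia or macrophages with their mixed barcodes 52.2% were mixed in CT and 49.5% in PD, against 23.2% and 25.1% for oligodendrocyte precursors. These ratios of 2.25 and 1.98 lie on either side of the bound of 2 set for the test, so chance doublets cannot be told apart from another origin. The test also rests on cluster 11.1, which held 104 of the 127 mixed precursor barcodes in CT and 35 of 103 in PD. Its origin is uncertain, because cluster 11.2, split from the same cluster, was led by the astrocyte marker GFAP. In SN PD, cluster 12.3 had a median of 2383 UMIs, against 912 in the leading microglia or macrophage cluster and 1074 in oligodendrocyte-like nuclei, or 1.1999 of their sum. That is consistent with RNA of 2 nuclei in 1 barcode, and no biological explanation was tested.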

How the results depend on the processing

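The automatic Scrublet calls, the additions of mixed and unnamed clusters, the changed divisions of SPN clusters and the reassigned thinned nuclei were chosen after the data were seen, as were the depth of thinning and the use of thinned counts within the reported classes. The other alternatives were fixed earlier. A value was taken to move when it left the 95% range of the reported one: exact counting intervals for ratios, Poisson redraws for list medians and redraws of genes for correlations. It was taken to turn when that range left out no difference and the value changed side. Of 198 share ratios under alternatives 157 stayed inside that range, 32 moved and 9 turned, and all 9 shares compared between regions within CT moved with at least 1000 genes. For list medians these counts were 2328, 125 and 22 of 2475, and for named genes 9651, 400 and 47 of 10098. Of 128 correlations between regions 45 moved and 0 turned. No list median or correlation moved with a prior of 5 UMIs. No paired analysis was possible because the files hold no map from barcodes to samples, and for the same reason no replicate was left out in turn. A setting in which a class was not named, or held too few nuclei or genes, gave no value. Thinning and the minimums of UMIs change which genes are measured, but for cholesterol synthesis in PUT direct SPNs neither set of members kept the reported value. Its median log2 was -0.58 over 15 members, -0.072 over the 6 measured with thinned nuclei, and -1.13 with thinned nuclei over the first 15. The minimums of UMIs leave each log2 ratio as it was, so under them a list median moved through its members alone, and medians over the first members stand below where thinning or other nuclei changed the members. No other cause was tested for a value that moved or turned. Below stand the reported values that turned, and those that moved among share ratios, CT shares, correlations and lists outside the central 95% range of random lists. Microglia or macrophage-like nuclei are called myeloid there, and oligodendrocyte precursor-like nuclei precursors.

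Nuclei with at least 200 genes gave share ratios of 0.393 (PUT astrocyte), 1.39 (PUT other neuron), 1.49 (CN oligodendrocyte), 0.0681 (CN astrocyte) and 0.0351 (CN eccentric SPN). CN other neuron was 0.993. SN other neuron was 0.919 (share ratios, on the other side of no difference). NR4A3 in CN direct SPN was 0.19 (gene log2 ratios, on the other side of no difference).

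Nuclei with at least 1000 genes gave share ratios of 1.49 (SN other neuron), 0.348 (SN myeloid), 0.866 (SN oligodendrocyte), 0.606 (PUT astrocyte) and 8.62 (CN oligodendrocyte). CN myeloid was 7.53 and CN direct SPN was 0.851. SN precursor was 1.25, PUT oligodendrocyte was 1.09, PUT myeloid was 0.748, CN precursor was 2.40 and CN astrocyte was 1.01 (share ratios, on the other side of no difference). SN oligodendrocyte was 52.2, SN myeloid was 1.79, SN precursor was 3.51, PUT oligodendrocyte was 12.6 and PUT myeloid was 0.406 (percent of CT nuclei). PUT precursor was 1.24, CN oligodendrocyte was 1.21, CN myeloid was 0.133 and CN precursor was 1.06. SLC4A4 in SN other neuron was -0.024 and PRDX1 in PUT oligodendrocyte was 0.012 (gene log2 ratios, on the other side of no difference). Parkinson disease in SN oligodendrocyte was -0.015 (0.056 over the first members), mitochondrially encoded in SN oligodendrocyte was 0.62 (0.65 over the first members), myelin in SN other neuron was -0.029 (-0.046 over the first members), disease microglia in PUT oligodendrocyte was -0.46 (-0.42 over the first members) and cholesterol synthesis in PUT oligodendrocyte was -0.72 (-0.56 over the first members) (log2 list medians). Nuclear respiratory chain in PUT oligodendrocyte was -0.17 (-0.24 over the first members), mitochondrially encoded in PUT oligodendrocyte was -1.13 (-1.27 over the first members) and synaptic vesicle in PUT oligodendrocyte was -0.26 (-0.30 over the first members). Disease microglia in SN oligodendrocyte was -0.16 and synaptic vesicle in SN oligodendrocyte was -0.035 (log2 list medians, on the other side of no difference). Oligodendrocyte SN and PUT was 0.322 (Spearman correlations).

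No doublet removal gave share ratios of 0.376 (SN astrocyte), 0.280 (SN myeloid), 0.810 (CN direct SPN) and 0.0631 (CN eccentric SPN). CLEC7A in SN myeloid was -0.025, GPC5 in SN myeloid was -0.23, HLA-E in SN myeloid was -0.17, MEF2C in SN myeloid was 0.052 and NLRC5 in SN myeloid was -0.46 (gene log2 ratios, on the other side of no difference). SCARB2 in SN myeloid was -0.16, SELPLG in SN myeloid was 0.010, SREBF2 in SN myeloid was 0.027 and GRIN2A in CN direct SPN was 0.057. Interferon response in SN myeloid was 0.26 (0.54 over the first members), myelin in SN dopamine neuron was -0.35 and myelin in SN other neuron was -0.10 (log2 list medians). Homeostatic microglia in SN myeloid was 0.010 and complement in SN myeloid was -0.032 (0.052 over the first members) (log2 list medians, on the other side of no difference). Myeloid SN and PUT was 0.256 (Spearman correlations).

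Automatic Scrublet calls gave share ratios of 1.22 (PUT indirect SPN) and 1.83 (CN oligodendrocyte). SN other neuron was 0.992 and PUT direct SPN was 0.986 (share ratios, on the other side of no difference). Myelin in SN dopamine neuron was -0.35 (log2 list medians). Direct SPN PUT and CN was 0.542 (Spearman correlations).

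Leiden resolution 2.0 gave share ratios of 0.327 (SN astrocyte), 0.840 (CN direct SPN) and 0.0693 (CN eccentric SPN).

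Clustering each region alone gave share ratios of 0.646 (CN other neuron). GPC5 in PUT myeloid was -0.0039, PDE10A in PUT myeloid was -0.015 and NR4A3 in CN direct SPN was 0.34 (gene log2 ratios, on the other side of no difference). Myelin in SN other neuron was -0.43 (log2 list medians). Myeloid SN and PUT was 0.148 (Spearman correlations).

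TMM scaling gave gene log2 ratios of 0.017 (IREB2 in CN indirect SPN), on the other side of no difference. Myelin in PUT oligodendrocyte was -0.057, cholesterol synthesis in CN direct SPN was -0.45 and cholesterol synthesis in CN indirect SPN was -0.48 (log2 list medians). Parkinson disease in CN direct SPN was 0.021, poly(ADP-ribose) in CN direct SPN was 0.025, lysosome in CN direct SPN was 0.023, synaptic vesicle in CN direct SPN was 0.025 and striatal dopamine in CN direct SPN was 0.079 (log2 list medians, on the other side of no difference). Parkinson disease in CN indirect SPN was 0.038, poly(ADP-ribose) in CN indirect SPN was 0.084, iron handling in CN indirect SPN was 0.0014, synaptic vesicle in CN indirect SPN was 0.064 and striatal dopamine in CN indirect SPN was 0.062.

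A minimum of 200 UMIs gave log2 list medians of 0.33 (interferon response in SN oligodendrocyte), -0.10 (cholesterol synthesis in PUT oligodendrocyte), -0.30 (nuclear respiratory chain in PUT oligodendrocyte), -0.26 (synaptic vesicle in PUT oligodendrocyte) and -0.17 (proteasome in CN oligodendrocyte). Oligodendrocyte SN and PUT was 0.370, oligodendrocyte SN and CN was 0.418, oligodendrocyte PUT and CN was 0.683, precursor PUT and CN was 0.442 and astrocyte PUT and CN was 0.6001 (Spearman correlations). Myeloid SN and PUT was 0.309, myeloid SN and CN was 0.409, myeloid PUT and CN was 0.554, direct SPN PUT and CN was 0.605 and indirect SPN PUT and CN was 0.611. Eccentric SPN PUT and CN was 0.489.

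A minimum of 10 UMIs gave log2 list medians of -0.44 (striatal dopamine in PUT oligodendrocyte), -0.085 (disease microglia in PUT indirect SPN) and -0.099 (MHC class I in CN indirect SPN). Disease microglia in PUT myeloid was 0.21 and reactive astrocyte in PUT direct SPN was 0.13 (log2 list medians, on the other side of no difference). Oligodendrocyte SN and PUT was 0.320, oligodendrocyte SN and CN was 0.332, oligodendrocyte PUT and CN was 0.498, precursor SN and CN was 0.109 and precursor PUT and CN was 0.184 (Spearman correlations). Astrocyte PUT and CN was 0.2197, myeloid SN and PUT was 0.165, myeloid SN and CN was 0.186, myeloid PUT and CN was 0.25 and direct SPN PUT and CN was 0.490. Indirect SPN PUT and CN was 0.517 and eccentric SPN PUT and CN was 0.234.

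Thinned nuclei gave share ratios of 1.98 (SN other neuron), 1.04 (PUT direct SPN) and 0.561 (CN indirect SPN). TGFBR1 in SN oligodendrocyte was -0.0015, PDE10A in SN precursor was -0.088, SHANK2 in SN other neuron was 0.18, SREBF2 in SN other neuron was -0.014 and VPS13C in SN other neuron was -0.14 (gene log2 ratios, on the other side of no difference). ATP6V0D1 in PUT direct SPN was 0.23, CPLX1 in PUT direct SPN was 0.23, FTL in PUT direct SPN was 0.044, GPC5 in PUT direct SPN was -0.015 and SLC4A4 in PUT direct SPN was -0.047. TAC1 in PUT indirect SPN was 0.016, GRIA1 in PUT eccentric SPN was -0.0017, FTH1 in CN indirect SPN was 0.042, PSMB7 in CN indirect SPN was -0.081 and VPS13C in CN eccentric SPN was 0.21. Interferon response in SN oligodendrocyte was 0.25 (0.78 over the first members), cholesterol synthesis in PUT oligodendrocyte was -0.16 (-0.41 over the first members), postsynaptic in PUT oligodendrocyte was 0.013, cholesterol synthesis in PUT direct SPN was -0.072 (-1.13 over the first members) and nuclear respiratory chain in PUT direct SPN was -0.12 (-0.42 over the first members) (log2 list medians). Cholesterol synthesis in PUT indirect SPN was -0.51 (-0.54 over the first members), disease microglia in CN oligodendrocyte was -0.28 (-0.24 over the first members), myelin in CN oligodendrocyte was 0.038 and cholesterol synthesis in CN indirect SPN was -0.49 (-0.53 over the first members). Parkinson disease in PUT indirect SPN was 0.017 (-0.15 over the first members), striatal dopamine in PUT indirect SPN was 0.0079 and proteasome in CN direct SPN was 0.15 (-0.10 over the first members) (log2 list medians, on the other side of no difference). Oligodendrocyte SN and PUT was 0.289, oligodendrocyte SN and CN was 0.338, oligodendrocyte PUT and CN was 0.517, precursor SN and CN was 0.107 and astrocyte PUT and CN was 0.331 (Spearman correlations). Direct SPN PUT and CN was 0.338, indirect SPN PUT and CN was 0.352 and eccentric SPN PUT and CN was 0.309.

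Reassigned thinned nuclei gave gene log2 ratios of 0.010 (ENPP2 in SN precursor), -0.36 (PDE10A in SN precursor), 0.27 (ATP6V0D1 in PUT direct SPN), 0.40 (CPLX1 in PUT direct SPN) and 0.090 (FTL in PUT direct SPN), on the other side of no difference. SLC4A4 in PUT direct SPN was -0.0084, MAOB in PUT indirect SPN was 0.11, MOBP in PUT indirect SPN was -0.033, HOMER1 in PUT eccentric SPN was -0.21 and CYC1 in CN direct SPN was 0.039. DLG2 in CN indirect SPN was -0.070, GRIN2B in CN indirect SPN was -0.37, GRM5 in CN indirect SPN was -0.17, SV2C in CN indirect SPN was -0.24 and SYN2 in CN indirect SPN was 0.66. VPS13C in CN eccentric SPN was 0.25. Interferon response in SN oligodendrocyte was 0.26 (0.68 over the first members), cholesterol synthesis in PUT oligodendrocyte was -0.17 (-0.43 over the first members), mitochondrially encoded in PUT oligodendrocyte was -0.75, cholesterol synthesis in PUT indirect SPN was -0.051 (-0.68 over the first members) and disease microglia in CN oligodendrocyte was -0.28 (-0.24 over the first members) (log2 list medians). Myelin in CN oligodendrocyte was 0.038. Homeostatic astrocyte in SN oligodendrocyte was 0.0033 (-0.098 over the first members), postsynaptic in PUT oligodendrocyte was -0.0073 and cell death in CN direct SPN was 0.029 (-0.17 over the first members) (log2 list medians, on the other side of no difference). Oligodendrocyte SN and PUT was 0.285, oligodendrocyte SN and CN was 0.337, oligodendrocyte PUT and CN was 0.515, precursor SN and PUT was 0.0642 and precursor SN and CN was 0.125 (Spearman correlations). Astrocyte PUT and CN was 0.329, myeloid SN and CN was 0.339, direct SPN PUT and CN was 0.376, indirect SPN PUT and CN was 0.291 and eccentric SPN PUT and CN was 0.305.

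Adding mixed clusters to their leading family gave share ratios of 1.16 (PUT precursor), 1.16 (PUT myeloid), 0.7003 (PUT astrocyte) and 1.43 (CN myeloid).

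Leaving out cluster 22.3 gave share ratios of 1.003 (PUT direct SPN).

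Direct SPN clusters of negative marker difference counted as indirect SPNs gave share ratios of 1.21 (PUT indirect SPN). PUT direct SPN was 0.984 (share ratios, on the other side of no difference).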

Other observations

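The values in this part were chosen after the data were seen, and no test was run on them. In SN, T-lymphocyte genes THEMIS and SKAP1 led the unnamed cluster 8.1, which held 19 nuclei of CT and 63 of PD. With unnamed clusters added by their leading genes, T or NK lymphocyte-like nuclei numbered 25 in CT and 128 in PD (share ratio 5.98, 3.87 to 9.59). Named astrocyte-like nuclei numbered 3 in SN CT and 5 in SN PD, too few for a comparison. With unnamed clusters added by their marker family they numbered 103 and 70 (share ratio 0.794), and with those added by their leading genes 291 and 138 (0.554, 0.449 to 0.681). Of the latter, cluster 11.2, led by GFAP, held 185 nuclei of CT and 52 of PD (0.328, 0.237 to 0.449). The ratio of named astrocyte-like nuclei was 0.376 with no doublet removal and 0.327 at Leiden resolution 2.0. The immunoglobulin gene IGKC stood higher in SN PD in each of 5 classes, but in 1 of them the interval held 1. It was 2.20 CPM in CT and 56.0 in PD in oligodendrocyte-like nuclei. In precursor-like nuclei it was 1.85 and 35.6 (1 and 16 UMIs, ratio 19.2, 2.98 to 806). In microglia or macrophage-like nuclei it was 39.0 and 65.2 (ratio 1.67, 0.985 to 2.87). In dopaminergic and other neuron-like nuclei IGKC had 0 UMIs in CT and 19 and 17 in PD. Background cannot be excluded for IGKC. In PD it had 398 UMIs in 5671 oligodendrocyte-like, 37 in 558 microglia or macrophage-like and 19 in 278 dopaminergic neuron-like nuclei. Their median depths were 1074, 912.5 and 14133 UMIs. Cluster 8.2, led by IRF4 and IGKC, held 48 nuclei of SN PD and 1 of SN CT. Within a region, log2 ratios of direct and indirect SPNs had a Spearman correlation across genes of 0.695 in PUT and 0.765 in CN, and those of dopaminergic and other neuron-like nuclei of SN one of 0.430. Unlike classes correlated too, at 0.495 for oligodendrocyte-like nuclei and direct SPNs of PUT and 0.389 for oligodendrocyte-like and dopaminergic neuron-like nuclei of SN. The lowest such value was 0.130, for astrocyte-like nuclei and eccentric SPNs of PUT. Classes of a region share both libraries.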
